A study of Sus scrofa with 12 samples.

How the data were processed

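RNA from the liver of 12 pigs was measured on the Affymetrix porcine array, 1 array per animal, without pooling. The deposited values were probe set signals as a linear intensity, made by the authors with GCOS 1.1.1 according to the submitters' notes on processing. How probes were summarised and arrays scaled was not given; the mean signal after trimming 2% was 500.2 on every array, so the values had been scaled per array before deposit, and they were used as deposited. All 12 columns were used. Groups were taken from the labels for stress response, aggressiveness and sex. No numbers paired the animals.

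Of 24123 probe sets, 124 Affymetrix controls were left out, and then 33.3% of the remaining 23999 with the lowest mean, so that 15999 were tested, with a mean signal of at least 40.58 (from the mean of log2 values). Signals were transformed as log2(signal + 16). Gene names came from the table of the array: 10099 probe sets had 1 symbol, 198 several and 13826 none, and those with several or none were tested without a name. A gene was represented by its kept probe set with the highest mean over the 12 arrays, which gave 5810 genes.

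limma 3.58.1 in R 4.3.3 was fitted to each probe set with stress response, aggressiveness and sex as terms, with 8 residual degrees of freedom. The interaction and the simple effects came from a second fit with the interaction added and 7 residual degrees of freedom. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05 over the 15999, and unadjusted p under 0.01 was counted as a descriptive second threshold. Fold changes are high against low, or males against females. Errors are the standard error (SE) of the log2 fold change, from limma's moderated variance, and the standard deviation (SD) of signals between animals. A list score is the mean over the members of the log2 value minus the mean of that gene over the 12 arrays.

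The comparisons, the 40 gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Lists of at least 5 measured genes, 38 in all, were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry; p-values were adjusted over the 38 lists. No list called for stress response or aggressiveness passed with an estimated correlation. With fry, which tests whether the genes of a list move on balance one way, the unfolded protein response and the list of glucocorticoid and catecholamine receptors and handling passed for stress response (adjusted p = 0.0241 for each), and no list passed for aggressiveness. Members of each list were also adjusted over the list alone. The list tests for the interaction and for sex were added after the data were seen.

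Named for stress response and for aggressiveness were the 10 genes higher and the 10 lower with the largest change past the threshold or, where too few passed, with the smallest p; list members past the threshold over the list alone; the 4 members with the smallest p of each called list; and 8 genes of glucocorticoid action. The interaction contributed 6 genes, each simple effect 3, and sex 5 in each direction with the measured genes of the Y chromosome. RNA quality was read from the log2 ratio of 3' to 5' control probe sets and compared between groups with exact permutation tests, two-sided. The 2 arrays with the lowest median correlation with the others were taken as standing apart, a number chosen after the data were seen.

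Alternatives were models without sex or the other factors, the interaction kept in the model, no filter, the lowest 50% left out, quantile normalization, median centring, trend and robust variance estimation (for lists the trend only), array weights, males only, added constants of 1 and 64, the mean over the probe sets of a gene, and each animal left out in turn. Added after the data were seen were the omission of both arrays that stood apart, the 3' to 5' ratio as a covariate, the constants of 1 and 64 for the simple effects, and the mean moderated t of each list against 72 balanced splits of the animals. Splits of the animals into groups of the same sizes were counted with the real split among them, 100 drawn for each comparison or, where fewer exist, all of them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

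The pipeline was tested on simulated data of the same layout. Of 67 probe sets given a log2 fold change of 0.5 between stress response groups, 12 were recovered (17.9%), of 67 given 1, 44 (65.7%), and of 66 given 2, 62 (93.9%), with 10 false calls among the rest. A simulated interaction of 2 was recovered in 136 of 200 probe sets with 2 false calls. A list shifted by 0.35, a size set near that seen for the unfolded protein response, was called by camera, and 0 of 36 other lists were. In these simulations values were drawn independently between genes. They therefore could not show how often camera calls lists of correlated genes. In the real data 22 of 72 balanced splits for stress response, the real one included, called at least 8 lists.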

Results

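Liver RNA from 12 German Landrace pigs was hybridized to the Affymetrix porcine array, with 1 array per animal. The pigs were labelled by 2 crossed factors, stress response (low or high) and aggressiveness (low or high), and each of the 4 combinations held 3 animals, 1 female and 2 males. Each level of a factor therefore held 6 animals. The series addresses psychosocial stress as seen in liver transcripts, and the labels do not say how stress response or aggressiveness was scored. Animals are named by stress response, aggressiveness and replicate, so that high-low 3 is the animal of replicate 3 with high stress response and low aggressiveness. Probe set signals ran from 0.149 to 66150, with a median per array between 93.3 and 117.4, and the number of arrays limits the precision. Log2 signals of any pair of arrays correlated at 0.945 to 0.975. The arrays of high-high 3, a female, and high-low 3, a male, stood apart, with median correlations of 0.953 and 0.957 with the others, and both belonged to the high stress response group. That of low-high 3, a female with low stress response and the highest median signal, was also 0.957 when rounded (0.9572 against 0.9567), so the line after 2 arrays was a choice.

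High against low stress response asked which liver transcripts went with the stress response of the animal, with aggressiveness and sex in the model. Genes of the unfolded protein response, which encode chaperones and regulators of protein folding in the endoplasmic reticulum, were higher as a group at high stress response. The 18 measured genes had a median log2 fold change of 0.35, with 16 above 0 and 2 below (camera, adjusted p = 9.81e-09, and adjusted p = 0.300 with an estimated correlation). HYOU1, a chaperone of the endoplasmic reticulum, had a signal of 2972 ± 777 (SD, n = 6) at high and 1730 ± 263 (SD, n = 6) at low stress response, a log2 fold change of 0.75 ± 0.14 (SE). MANF, a secreted protein induced by stress of the endoplasmic reticulum, had signals of 11600 ± 3117 and 6955 ± 537 (SD, n = 6 each), a log2 fold change of 0.70 ± 0.14 (SE). HSPA5, the main chaperone of this compartment, had signals of 28730 ± 3625 and 21520 ± 1377 (SD, n = 6 each), a log2 fold change of 0.41 ± 0.12 (SE). Adjusted over the list alone, 7 genes passed, all of them higher: HYOU1, MANF, CRELD2, SDF2L1, DNAJC3, HSPA5 and DDIT3, with log2 fold changes from 0.38 to 0.89. A second probe set of DNAJC3 had -0.05 ± 0.17 (SE), against 0.38 for the one counted. In each of these 7 genes all 6 animals with high stress response lay above the median of the low group. None of the 18 passed over all 15999 probe sets. Without the 2 arrays that stood apart, a setting chosen after the data were seen, the median of the list was 0.28 (adjusted p = 6.21e-08).

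**Figure D1:**
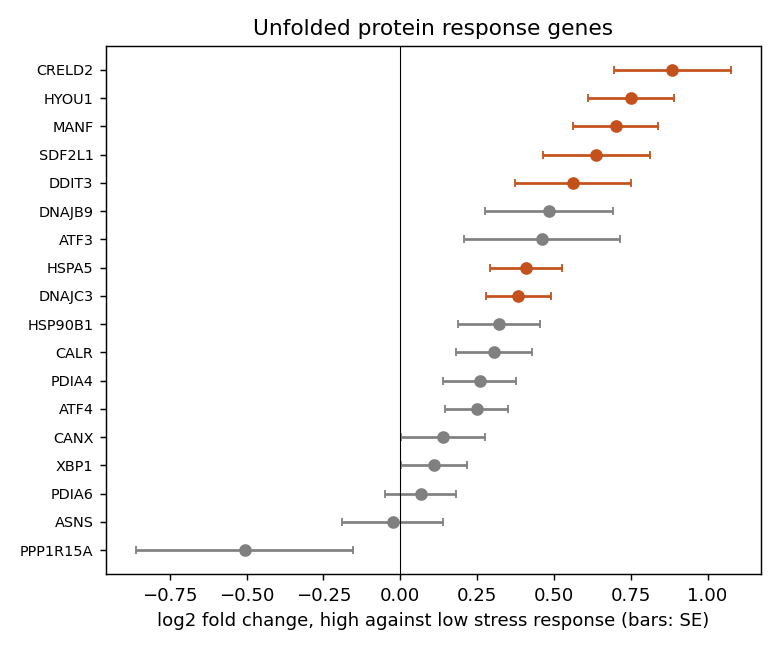
Log2 fold change at high against low stress response (horizontal axis) of the 18 measured genes of the unfolded protein response, with bars of 1 SE, from all 12 arrays. The 7 genes in orange passed when adjusted over the list alone, and 16 of the 18 points lie above 0.

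Genes of sterol and lipid metabolism were lower as groups at high stress response. Of 13 genes of cholesterol synthesis, 12 were below 0, with a median log2 fold change of -0.26 (camera, adjusted p = 0.0012, and adjusted p = 0.501 with an estimated correlation). FDFT1, squalene synthase, had signals of 3241 ± 1136 at high and 5591 ± 953 at low stress response (SD, n = 6 each), a log2 fold change of -0.82 ± 0.20 (SE). Animal high-low 2 lay far above the other 5 of the high group. SQLE, squalene epoxidase, had signals of 1031 ± 249 and 1797 ± 584 (SD, n = 6 each). Adjusted over the list alone, FDFT1 and SQLE passed as lower and HSD17B7, a later enzyme of the same pathway, as higher, with a log2 fold change of 1.23 ± 0.37 (SE). Of 17 genes of fatty acid and triglyceride synthesis, 14 were below 0, with a median of -0.28 (adjusted p = 0.0050, and adjusted p = 0.650 with an estimated correlation). In that list DGAT2, which makes triglycerides, had a log2 fold change of -1.10 ± 0.36 (SE), and the fatty acid desaturases FADS2 and FADS1 had -1.50 ± 0.51 and -1.41 ± 0.53 (SE). None of its members passed when adjusted over the list alone. Of 24 genes of fatty acid oxidation and ketogenesis, 19 were below 0, with a median of -0.15 (adjusted p = 0.0112, and adjusted p = 0.857 with an estimated correlation). Among them were PPARA, the nuclear receptor of this pathway, at -0.55, and FABP1, the liver fatty acid binding protein, at -0.47. Without the 2 arrays that stood apart the calls of all 3 lists ended. Their medians were then -0.19 (adjusted p = 0.0562) for cholesterol synthesis, -0.14 (adjusted p = 0.186) for fatty acid and triglyceride synthesis and -0.06 (adjusted p = 0.130) for fatty acid oxidation and ketogenesis. The call for fatty acid oxidation also ended without low-low 1 (-0.09, adjusted p = 0.146) or high-high 3 (-0.07, adjusted p = 0.0667) and under quantile normalization (-0.11, adjusted p = 0.0658). Without high-low 3 its median was -0.10. In males alone the calls of fatty acid and triglyceride synthesis (-0.13, adjusted p = 0.0927) and of fatty acid oxidation and ketogenesis (-0.04, adjusted p = 0.47) ended. The median of cholesterol synthesis was then -0.16 (adjusted p = 0.0182).

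Genes of bile acid synthesis and transport and of cytochrome P450 xenobiotic metabolism were also lower as groups. All 6 measured genes of bile acid synthesis and transport were below 0, with a median log2 fold change of -0.59 (camera, adjusted p = 7.37e-04, and adjusted p = 0.369 with an estimated correlation). ABCB11, the bile salt export pump, had signals of 179 ± 59.0 at high and 289 ± 39.4 at low stress response (SD, n = 6 each). It was lower when adjusted over the list alone, with a log2 fold change of -0.69 ± 0.20 (SE). The others named were AMACR at -0.70, SLC10A1, the bile acid uptake carrier, at -0.49, and ABCC2 at -0.43. Without high-low 3 AMACR was -0.44 and SLC10A1 -0.31, and without high-high 3 SLC10A1 was -0.25. Of 18 genes of cytochrome P450 xenobiotic metabolism, 14 were below 0, with a median of -0.24 (adjusted p = 0.0041, and adjusted p = 0.427 with an estimated correlation). CYP1A1, CYP2B22, CYP2A19 and FMO5, all enzymes of drug oxidation, had log2 fold changes of -1.37, -0.79, -0.59 and -0.59, and none passed when adjusted over the list alone. CYP2A19 was -0.25 without high-low 3, which lay far below the rest of its group. The list of conjugation and phase II enzymes, also of drug metabolism, was not called (median -0.10 over 12 genes, adjusted p = 0.265). Without the 2 arrays that stood apart the bile acid list had a median of -0.39 (adjusted p = 0.0441), while the call of cytochrome P450 xenobiotic metabolism ended (-0.10, adjusted p = 0.113). That call ended in males alone as well (adjusted p = 0.0860), and its median was -0.14 without high-low 3 and -0.16 without high-high 3.

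**Figure D2:**
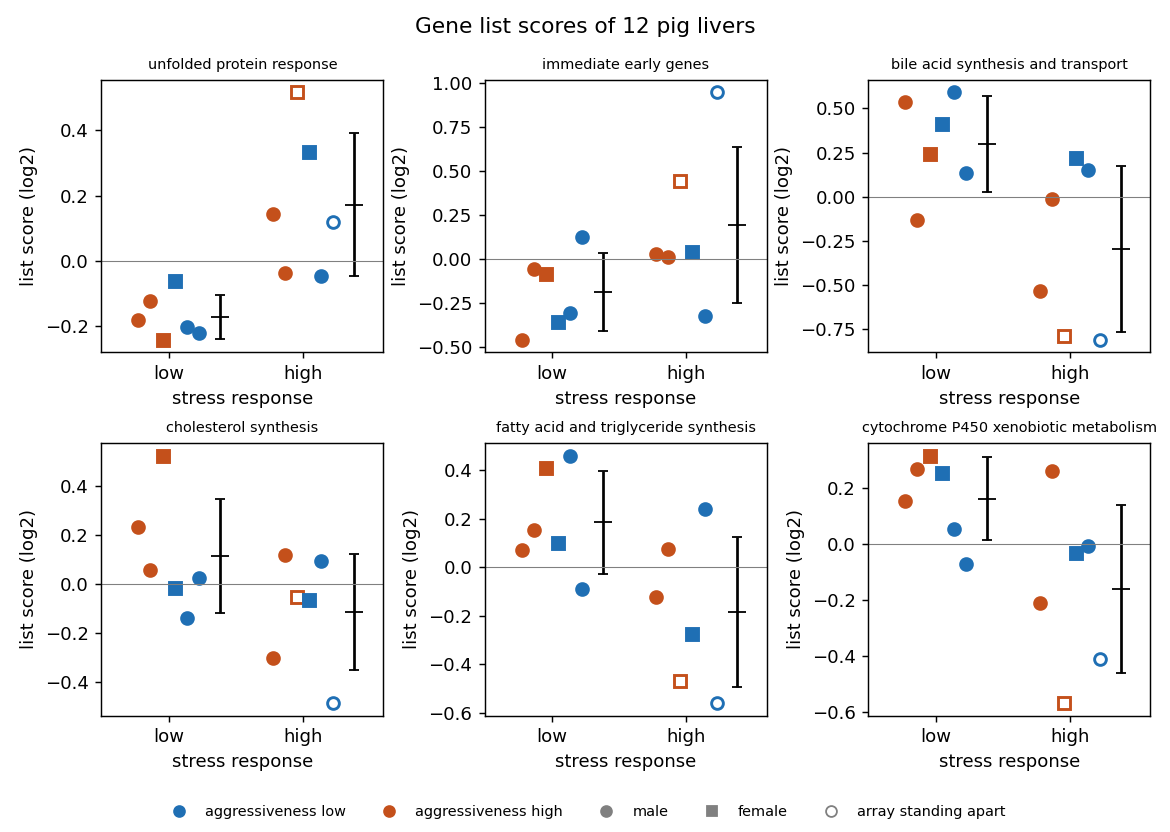
Scores of 6 gene lists (vertical axis, log2, mean over the list of each gene's value minus its mean over all arrays) in the 12 livers by stress response, with colour for aggressiveness, shape for sex, open symbols for the 2 arrays that stood apart, and the mean with bars of 1 SD for each group of 6. For the unfolded protein response all 6 animals with high stress response lie above the highest of the low group.

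Immediate early genes, which are transcribed within minutes of a stimulus, were higher as a group at high stress response. Of 14 genes 12 were above 0, with a median log2 fold change of 0.42 (camera, adjusted p = 0.0041, and adjusted p = 0.857 with an estimated correlation). KLF4, FOS, NR4A2 and IER2 had log2 fold changes of 0.66, 0.73, 0.49 and 0.40, and none passed when adjusted over the list alone. NR4A2 was 0.28 without low-low 1. The 2 arrays that stood apart held the highest scores of this list, and without them its call ended (0.10, adjusted p = 0.317), while its median was 0.25 without high-low 3 and 0.27 without high-high 3. The list of glucocorticoid and catecholamine receptors and handling was lower as a group, with 10 of 16 genes below 0 and a median of -0.20 (adjusted p = 0.0212, and adjusted p = 0.300 with an estimated correlation). Adjusted over the list alone, SERPINA6, the globulin that carries cortisol in blood, was lower, with a log2 fold change of -1.06 ± 0.31 (SE), and so was AKR1C1, a steroid reductase, at -0.76 ± 0.19 (SE). SERPINA6 had signals of 2358 ± 1412 at high and 4493 ± 1010 at low stress response (SD, n = 6 each). The call of this list ended under quantile normalization (adjusted p = 0.0519), with the lowest 50% of the probe sets left out (-0.10, adjusted p = 0.0710) and without the 2 arrays that stood apart (-0.13, adjusted p = 0.0722). Its median was -0.12 without high-low 2, -0.13 without high-high 3 and -0.08 in males alone.

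Genes induced by glucocorticoids did not pass as a group, with a median log2 fold change of 0.10 over 20 genes (camera, adjusted p = 0.439). FKBP5 and PER1, both induced by glucocorticoids, had log2 fold changes of 0.74 ± 0.42 and 0.23 ± 0.19 (SE), TSC22D3 had -0.42 ± 0.18 (SE), and TAT, tyrosine aminotransferase, had -0.14 ± 0.25 (SE). PCK1, the key enzyme of gluconeogenesis, had 0.01 ± 0.10 (SE) and was -0.03 under median centring. NR3C1, the glucocorticoid receptor, had 0.08 ± 0.18 (SE), and HSD11B1, which regenerates cortisol, had -0.25 ± 0.14 (SE). Second probe sets had 0.47 ± 0.28 for NR3C1, 0.42 ± 0.24 for FKBP5 and 0.01 ± 0.16 (SE) for TAT. FKBP5 was 0.47 without high-low 3, HSD11B1 -0.14 without high-high 3 and TAT -0.03 without low-low 3. The acute phase list did not pass either (0.10 over 17 genes, adjusted p = 0.0784). Within it CRP, a plasma protein of inflammation, was higher when adjusted over the list alone (adjusted p = 0.0059). CRP had signals of 21920 ± 6022 at high and 8295 ± 4969 at low stress response (SD, n = 6 each), a log2 fold change of 1.54 ± 0.31 (SE). Hepatocyte markers had a median of 0.07 (adjusted p = 0.824), and the markers of Kupffer cells, endothelial cells, stellate cells and cholangiocytes had medians of 0.05, -0.03, 0.08 and 0.13, with none of these lists called. Within the cholangiocyte list KRT18, a keratin also made by hepatocytes, was higher (0.98 ± 0.28, SE) and PROM1 lower (-1.07 ± 0.34, SE) when adjusted over the list alone.

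**Figure D3:**
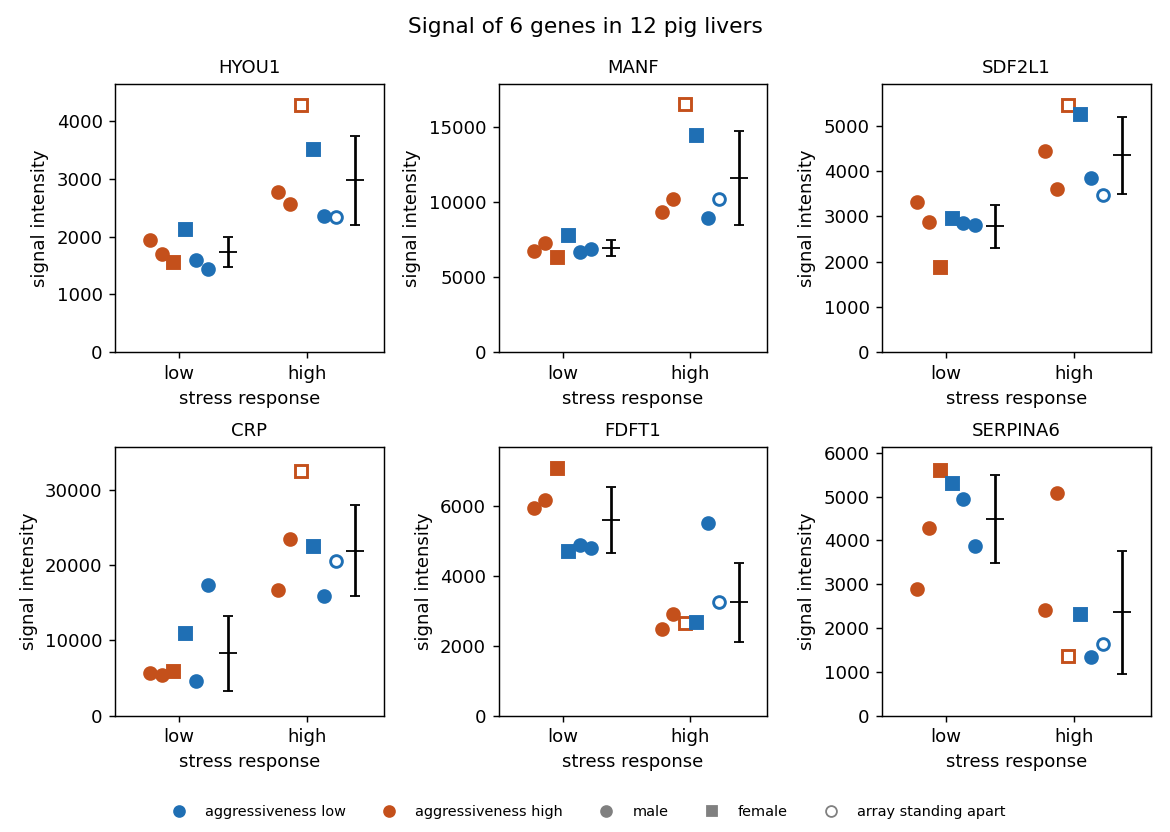
Signal intensity (vertical axis, linear scale from 0) of HYOU1, MANF, SDF2L1, CRP, FDFT1 and SERPINA6 in the 12 livers by stress response, with colour for aggressiveness, shape for sex, open symbols for the 2 arrays that stood apart, and the mean with bars of 1 SD for each group of 6. Every animal with high stress response lies above every animal of the low group for HYOU1, MANF and SDF2L1, while the groups overlap for CRP, FDFT1 and SERPINA6.

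With limma, 0 of 15999 probe sets passed for stress response over all probe sets, with a smallest adjusted p of 0.339, and 1305 had an unadjusted p under 0.05, against 800 expected by chance. At an unadjusted p under 0.01 there were 306, 199 higher and 107 lower (65.0% higher), against 160 expected; under median centring there were 118 higher and 144 lower (45.0% higher). The 10 genes with the smallest p among those higher, none of them past the threshold over all probe sets, were RAD54L, HYOU1, CLSTN3, MANF, CRP, LRRC59, NANS, CRELD2, GRWD1 and TFPT, with log2 fold changes from 0.52 to 1.54. At low stress response RAD54L and TFPT had mean signals of 30.6 and 38.7, below the lowest mean signal of a tested probe set, 40.58. The 10 lower genes with the smallest p were FBP2, CCDC28A, LOC102164640, MARVELD3, FDFT1, AKR1C1, TMEM14A, IFT46, PON3 and DDO, with log2 fold changes from -1.17 to -0.47. FBP2, the muscle form of fructose bisphosphatase, had the smallest p of these, with signals of 157 ± 54.3 at high and 362 ± 45.3 at low stress response (SD, n = 6 each). FBP2 passed without high-low 2 (adjusted p = 0.0121) and CRP without low-low 3 (adjusted p = 0.0383), and the 306 probe sets became 154 without high-high 3 and 199 without high-low 3. There were 135 without both of these arrays and 142 in males alone, both below the 160 expected by chance.

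High against low aggressiveness asked the same of the other factor, with stress response and sex in the model. Interferon-stimulated genes, which act in antiviral defence, were higher as a group at high aggressiveness. Of 19 genes 17 were above 0, with a median log2 fold change of 0.22 (camera, adjusted p = 0.0152, and adjusted p = 0.928 with an estimated correlation). DDX58, a sensor of viral RNA, had signals of 445 ± 185 at high and 292 ± 94.8 at low aggressiveness (SD, n = 6 each). MX1, an antiviral GTPase, had a log2 fold change of 0.57 ± 0.38 (SE), and STAT2 and MX2 had 0.26 and 0.23. MX1 was 0.28 without low-low 1 and 0.38 without low-high 3, STAT2 0.15 without low-low 1 and MX2 0.13 without high-low 3. Cholesterol synthesis was higher as a group, with 12 of 13 genes above 0 and a median of 0.15, and HMGCS1, SC5D, CYP51 and HSD17B7 had 0.38, 0.30, 0.31 and 0.63. HSD17B7 was 0.30 without low-low 1. The acute phase list was higher, with 14 of 17 genes above 0 and a median of 0.14, as were the hepatocyte markers, with 10 of 13 above 0 and a median of 0.11. Each of these last 3 lists had an adjusted p of 0.0189, 0.0189 and 0.0316 in turn, and an adjusted p of 0.928 with an estimated correlation. Members named from the last pair were A2M, FGG, FGB, HPX, APOB, TF and SERPINA1, all secreted by hepatocytes, with log2 fold changes from 0.13 to 0.19 and mean signals near the top of the scale. APOB was 0.11 without high-low 1, and HPX and TF were both 0.09 without low-high 3. A second probe set of FGG had -0.08 ± 0.46 (SE). No member of the 4 lists passed when adjusted over the list alone. Outside these lists NCF4, a subunit of the phagocyte oxidase, was higher when adjusted over the list alone, that of neutrophil markers. It had signals of 118 ± 15.4 and 85.9 ± 8.01 (SD, n = 6 each) and a log2 fold change of 0.39 ± 0.11 (SE). Of the 9 genes of that list 6 were below 0, and the list was not called (median -0.09, mean -0.02, camera direction higher, adjusted p = 0.903).

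The control transcript EF1A had a higher log2 ratio of its 3' to its 5' signal, a sign of RNA quality, at high aggressiveness (0.892 ± 0.0878) than at low (0.721 ± 0.0258; SD, n = 6 each). The exact permutation test, two-sided, gave p = 0.00217 and adjusted p = 0.0260 over 12 tests. Every animal with high aggressiveness lay above every animal with low (lowest 0.757 against highest 0.748), so this p is the lowest the test allows. The ratio of GAPDH (0.830 ± 0.160 against 0.785 ± 0.120), that of actin (5.10 ± 0.243 against 5.07 ± 0.333) and the mean of the control ratios (2.28 ± 0.105 against 2.19 ± 0.119; SD, n = 6 each) did not pass. Their exact p was 0.593, 0.862 and 0.227 (adjusted p = 0.857, 0.875 and 0.857). With the mean 3' to 5' ratio as a covariate, a setting added after the data were seen, the call ended for interferon-stimulated genes (0.13, adjusted p = 0.113) and cholesterol synthesis (0.13, adjusted p = 0.113). It ended there too for the acute phase response (0.11, adjusted p = 0.0926) and hepatocyte markers (0.07, adjusted p = 0.359). That covariate was the mean of the control ratios, which itself did not pass. The EF1A ratio alone was not fitted as a covariate. Under quantile normalization the acute phase response (0.04, adjusted p = 0.588) and the hepatocyte markers (0.02, adjusted p = 0.611) lost their calls. In males alone the calls of cholesterol synthesis (0.17, adjusted p = 0.153), the acute phase response (0.09, adjusted p = 0.163) and the hepatocyte markers (0.08, adjusted p = 0.243) ended. The acute phase response lost its call with the mean over the probe sets of a gene (0.13, adjusted p = 0.0566), where the median of cholesterol synthesis was 0.08, and the hepatocyte markers lost theirs without the filter (adjusted p = 0.0695) at an unchanged median of 0.11. Without the 2 arrays that stood apart all 4 calls held. The acute phase response and the hepatocyte markers then had medians of 0.21 (camera, adjusted p = 0.0063) and 0.17 (adjusted p = 0.0125). Each call ended, however, in some fits without 1 animal. That of interferon-stimulated genes ended without any of low-low 1 (adjusted p = 0.0904), low-low 2 (0.0859), low-high 3 (0.144), high-high 1 (0.216), high-low 2 (0.0846) or high-low 3 (0.0561), with medians from 0.11 to 0.16. That of cholesterol synthesis ended without any of low-low 1 (adjusted p = 0.0614), low-high 1 (0.0758), low-low 2 (0.111), low-high 3 (0.240), high-high 2 (0.206) or high-low 3 (0.170). Its medians in these fits were 0.12 to 0.20, around the 0.15 of all animals, and its median was 0.25 without high-high 1 (adjusted p = 0.0022). The acute phase response lost its call without any of low-high 1 (adjusted p = 0.0942), low-low 2 (0.124), high-low 1 (0.114), high-high 2 (0.206) or high-low 2 (0.105), with medians from 0.11 to 0.12. The hepatocyte markers lost theirs without any of low-high 1 (adjusted p = 0.0802), low-low 2 (0.135), low-high 3 (0.240), high-low 1 (0.216), high-high 2 (0.194) or high-low 2 (0.0738), with medians from 0.08 to 0.13.

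With limma, 0 probe sets passed for aggressiveness over all 15999, with a smallest adjusted p of 0.553, and 515 had an unadjusted p under 0.05. At an unadjusted p under 0.01 there were 82, 50 higher and 32 lower (61.0% higher), below the 160 expected by chance; the split was 48 and 47 under quantile normalization (50.5% higher). Fewer were higher than lower with the lowest 50% left out (19 and 26), in males alone (48 and 66), without low-high 3 (34 and 54) and without high-high 1 (34 and 38). The 10 genes with the smallest p among those higher, none past the threshold, were WAS, SSTR1, SLMAP, NCF4, DCHS1, NPPA, HSD11B2, EDRF1, TMEM151B and ENO3. At low aggressiveness SSTR1, SLMAP and NPPA had mean signals of 29.7, 29.4 and 32.2, below the lowest mean signal of a tested probe set, 40.58. WAS, an actin regulator of blood cells, had signals of 160 ± 30.7 at high and 95.9 ± 20.1 at low aggressiveness (SD, n = 6 each). HSD11B2, which inactivates cortisol, had 117 ± 17.4 and 84.4 ± 15.9 (SD, n = 6 each). Those lower were PJA1, CDHR4, MAL2, SH3BGRL2, MAGEH1, MDK, TFPI2, DPT, NRAP and NKIRAS1, with log2 fold changes from -1.14 to -0.34. NRAP had a mean signal of 32.1 at high aggressiveness and was dim too. Second probe sets of PJA1, SH3BGRL2 and NKIRAS1 had 0.07 ± 0.22, 0.06 ± 0.12 and -0.04 ± 0.20 (SE). NR3C1, SERPINA6, FKBP5 and PCK1 had log2 fold changes of -0.28 ± 0.18, 0.19 ± 0.31, -0.38 ± 0.42 and 0.17 ± 0.10 (SE). Second probe sets of NR3C1 and FKBP5 went the other way, with 0.11 ± 0.28 and 0.42 ± 0.24 (SE). FKBP5 was -0.22 without high-high 1 and -0.11 without high-high 2 or high-low 3. HSD11B1, TSC22D3 and PER1 had -0.05 ± 0.14, -0.02 ± 0.18 and 0.06 ± 0.19 (SE), and TAT had -0.01 ± 0.25 (SE), with 6e-04 under quantile normalization.

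The interaction asked whether the effect of stress response differed between the levels of aggressiveness, and the simple effects gave each factor within a level of the other. PRKAG3, a regulatory subunit of AMP-activated protein kinase, had a signal of 31 ± 6.5 in the animals with high stress response and high aggressiveness and 121 ± 32.7 in those with high stress response and low aggressiveness (SD, n = 3 each). It was lower at high aggressiveness within the high stress response group (log2 fold change -1.52 ± 0.18, SE, adjusted p = 0.0480, lower in 3 of 3 animals). Its signal was 113 ± 26.4 and 103 ± 15.7 in the low stress response groups (SD, n = 3 each). In the same contrast 1 probe set of ZNF281, a zinc finger transcription factor, had signals of 23.8 ± 4.94 and 151 ± 41.5 (SD, n = 3 each; -2.04 ± 0.20, SE, adjusted p = 0.0180). ZNF281 was named after its values were seen, and the ZNF281 probe set with the highest mean signal had a log2 fold change of 0.21 ± 0.25 (SE). The signals of 31 and 23.8 lay below the lowest mean signal of a tested probe set, 40.58, so the size of both folds depended on the constant added before the log. With a constant of 64 in place of 16, a setting added after the data were seen, PRKAG3 was -0.95 (adjusted p = 0.373) and ZNF281 -1.27 (adjusted p = 0.0790). With a constant of 1 they were -1.92 (adjusted p = 0.0199) and -2.59 (adjusted p = 0.0093). With the constant of 16 these were the 2 probe sets past the threshold in the 4 simple effects. The other contrasts gave 0 with limma, with 819, 980 and 511 probe sets at an unadjusted p under 0.05 for stress response at low and at high aggressiveness and for aggressiveness at low stress response.

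OGDHL, which resembles a subunit of the oxoglutarate dehydrogenase complex, had signals of 1052 ± 176 at high stress response and high aggressiveness and 1304 ± 263 at low stress response and low aggressiveness (SD, n = 3 each). In the mixed groups high-low and low-high the signals were 446 ± 411 and 292 ± 105 (SD, n = 3 each). Its interaction was 3.68 ± 0.68 (log2, SE) and did not pass. The other genes with the smallest p were PRKAG3 (-1.63), RGS16 (2.38), GRK5 (-1.38), IGFBP6 (-2.03) and GNG3 (-1.86). For the interaction limma gave 0 probe sets, with 619 at an unadjusted p under 0.05. At an unadjusted p under 0.01 there were 38 higher and 66 lower (36.5% higher), against 67 and 49 under median centring (57.8% higher). More were higher than lower also without high-low 3 (83 and 63), without low-high 3 (57 and 53) and without both arrays that stood apart (60 and 58). The genes with the smallest p in the simple effects were PROM1, RGS16 and GNG3 for stress response at low aggressiveness and PRKAG3, PLCD1 and FDFT1 at high aggressiveness. Those for aggressiveness were ITIH5, MAPRE3 and OXTR at low stress response and PRKAG3, RGS16 and PROM1 at high stress response. A second probe set of PLCD1 had -0.20 ± 0.40 (SE), against -1.03 for the one named. FDFT1 had 2679 ± 210 against 6387 ± 602 at high aggressiveness (SD, n = 3 each; log2 fold change -1.25 ± 0.24, SE). With 3 animals against 3, an exact test could not go below 0.1. When single animals were left out, ZNF281 was called in 5 of 12 fits, each without an animal of low stress response, which is outside the contrast. Without any 1 of the 6 animals compared it was not called. PRKAG3 was called in 1 fit, that without high-low 3 (adjusted p = 0.0302). Without low-high 1 the interaction called RGS16 (adjusted p = 0.0335), as did aggressiveness at high stress response (adjusted p = 0.0283). Without high-low 3 the interaction called OGDHL (adjusted p = 0.0199) and stress response at high aggressiveness called PRKAG3 (adjusted p = 0.0472).

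Males against females compared 8 with 4 animals, with both factors in the model, and checked the labels. EIF1AY, a translation factor on the Y chromosome and the measured gene of the list fixed for that chromosome, had a signal of 507 ± 87.4 in males (SD, n = 8) and 8.32 ± 4.37 in females (SD, n = 4), with no overlap between the labelled sexes. Its log2 fold change was 4.43 ± 0.17 (SE, adjusted p = 9.74e-08). With limma 11 probe sets passed, 6 higher and 5 lower in males. Of these 2 had a gene name, EIF1AY and CLSTN3, and 9 had none. CLSTN3, a calsyntenin, had signals of 141 ± 46.0 in males (SD, n = 8) and 61.0 ± 30.6 in females (SD, n = 4), a log2 fold change of 1.04 ± 0.16 (SE, adjusted p = 0.0496). Its call was lost in 11 of 12 fits without 1 animal, with an adjusted p of up to 0.221. KDM6A and TXLNG, both on the X chromosome, had log2 fold changes of -0.88 ± 0.15 and -0.59 ± 0.12 (SE) and did not pass. RHBG, LPIN2 and ZNF219 (0.97, 0.71 and 0.56) and CDKN1A, VPS36 and RRP7A (-0.91, -0.54 and -0.61) did not pass either. At an unadjusted p under 0.01 there were 95 higher and 89 lower in males (51.6% higher), against 132 and 59 under quantile normalization (69.1% higher) and 146 and 47 under median centring (75.7% higher). Fewer were higher than lower without the filter (121 and 181), with an added constant of 64 (92 and 96) and without both arrays that stood apart (98 and 100). The same held without low-low 3 (89 and 107), high-low 1 (88 and 115), high-high 1 (85 and 101), high-low 2 (84 and 86) or high-low 3 (97 and 135).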

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

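The tests without both arrays that stood apart, both tests of the share of hepatocytes and the list tests of the interaction were chosen only after the results were seen.

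The unfolded protein response list was higher at high stress response, with a median log2 fold change of 0.35. The values argue against both arrays that stood apart as its whole cause. Its call held without those arrays (0.28, camera at the preset correlation). With an estimated correlation camera gave the list an adjusted p of 0.300 on all arrays. The call held too with the score of 13 immediate early genes as a covariate (0.30, camera, adjusted p = 3.13e-07). The immediate early list itself differed largely through both arrays, with a median of 0.42 with them and 0.10 without. Among the other animals that covariate had little to take out. This test therefore cannot decide on tissue handling, which the labels did not record. With the mean 3' to 5' ratio of the control transcripts as a covariate, against RNA degradation, the call of the unfolded protein response list also held (0.34). That ratio hardly differed, with 2.22 ± 0.139 at high and 2.25 ± 0.0944 at low stress response (SD, n = 6 each). The exact permutation test gave p = 0.630 (adjusted p = 0.857). The covariate thus had little to take out, and this test cannot decide. Among 72 balanced splits the real one gave the mean moderated t farthest from 0 (1 of 72, 2.59 against 1.93 for the highest other). That share, 0.0139, lay under 0.05 but is the lowest that 72 splits allow. The list was also picked, in the same data, for its call among 38 lists. Adjusted over the 38 lists the share was 0.264, and this adjustment could not have passed for a single list. Chance therefore cannot be excluded. Besides chance, RNA degradation and tissue handling, a biological difference between animals with high and low stress response stays open, as a hypothesis only. Another trait that went with the label stays open too.

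Cholesterol synthesis together with fatty acid and triglyceride synthesis was lower at high stress response, with a median log2 fold change of -0.27 over 30 genes. A lower share of hepatocytes could give this. The 13 hepatocyte markers had a median of 0.07, which lay 0.33 ± 0.062 above that of both lists (SE from resampling list members 10000 times). These medians go against a lower share, though abundant markers lay near the top of the scale. The error treats genes as replicates and holds no spread between the 12 animals, so this test cannot decide. The first test of that share did not decide, since 1 of the 4 marker lists of other cell types had a median at or below 0. Whether both arrays that stood apart account for the pattern cannot be told apart from the label: without them the median was -0.14, and the smaller adjusted p of the lists was 0.0562, with both arrays in the high stress response group. Among 72 balanced splits, the real one included, 7 moved cholesterol synthesis as far from 0 (mean moderated t 1.40, highest other 1.91). For fatty acid and triglyceride synthesis 10 of 72 did so (1.01, highest other 1.66). Chance therefore cannot be excluded for either list. The biological difference named by the label stays open, untested.

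Immediate early genes were higher at high stress response, with a median log2 fold change of 0.42, and without both arrays that stood apart the median was 0.10 and the call ended. Both arrays were in the high stress response group and held the highest scores of the list, so leaving them out would lower the difference whatever its cause. Whether those arrays account for the pattern therefore cannot be told apart from the label. Among 72 balanced splits, the real one included, 5 gave a mean moderated t as far from 0 (1.46, against 2.13 for the highest other). That share was 0.0694, and 0.528 when adjusted over the 38 lists, so chance cannot be excluded. Tissue handling was not recorded in the labels, so chance, a difference in handling and one in biology all stay open.

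Counts were compared with splits of the same animals, the real one included in each count. Chance cannot be excluded for the 306 probe sets at an unadjusted p under 0.01 for stress response, since 6 of 100 splits gave as many (highest other 592), nor for the 82 for aggressiveness (93 of 100, highest other 547) and the 104 for the interaction (78 of 100, highest other 426). For aggressiveness and the interaction the highest of these is several times the real count, and why was not tested. Chance cannot be excluded for the number of lists called either, with 8 for stress response (22 of 72 splits, highest other 14), 4 for aggressiveness (41 of 72, highest other 12), 5 for sex (57 of 100, highest other 14) and 2 for the interaction (88 of 100, highest other 13). Chance can be excluded for the 11 probe sets for sex (1 of 100 splits, highest other 3). For the 2 probe sets for aggressiveness at high stress response the 10 splits were too few for a share under 0.05 (1 of 10, highest other 1). The list of glucocorticoid and catecholamine receptors and handling for stress response was farthest from 0 in the real split (1 of 72, adjusted share 0.264). So was that of negative acute phase proteins for aggressiveness (1 of 72, adjusted share 0.528, camera adjusted p = 0.0570). Other lists called for stress response moved as far in 3 of 72 splits (bile acids), 5 (immediate early genes) and 7 (cholesterol synthesis). Cytochrome P450, fatty acid synthesis and fatty acid oxidation did so in 8, 10 and 17. For aggressiveness the numbers were 5 (hepatocyte markers), 9 (acute phase), 15 (cholesterol synthesis) and 23 (interferon-stimulated genes). Adjusted shares were 0.396 to 0.693 and 0.920, so chance cannot be excluded for these lists.

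The effect of stress response on 2 gene lists differed between the levels of aggressiveness by camera on the interaction. The 55 ribosomal protein genes had a median log2 difference of -0.15 (adjusted p = 9.13e-05, and adjusted p = 0.985 with an estimated correlation). Their median effect was 0.08, with 49 genes above 0, at low aggressiveness and -0.07, with 6 above 0, at high aggressiveness. This call ended without low-low 2 (-0.10, adjusted p = 0.0530), without both arrays that stood apart (-0.04, adjusted p = 0.643) and under quantile normalization (-0.05, adjusted p = 0.238). The median was -0.10 without high-low 3 and -0.08 under median centring. The 17 markers of stellate cells and fibroblasts, collagens and contractile proteins among them, had a median difference of -0.55 (adjusted p = 0.0032, and adjusted p = 0.985 with an estimated correlation). Their median effect was 0.45, with 15 genes above 0, at low aggressiveness and -0.11, with 1 above 0, at high aggressiveness. This call ended without low-low 2 (-0.36, adjusted p = 0.0754), high-low 1 (-0.35, adjusted p = 0.0654), high-low 3 (-0.40, adjusted p = 0.0552) or both arrays that stood apart (-0.39, adjusted p = 0.319).

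In 15 of 270 groups of animals the highest or lowest animal lay far from the others by the gap to its nearest neighbour as a share of the range of the group, against 13.5 expected by chance at 1 in 20. Among animals with high stress response, the share was 0.667 for FDFT1 (high-low 2 highest), 0.636 for IFT46 and 0.643 for HSD11B1 (high-high 3 lowest in both), 0.720 for CYP2A19 (high-low 3 lowest) and 0.821 for the score of glucocorticoid and catecholamine receptors and handling (high-low 1 highest). Among animals with low stress response it was 0.636 for FMO5 (low-low 3 highest), 0.712 for SDF2L1 (low-high 3 lowest), 0.717 for NR4A2 (low-low 1 lowest), 0.665 for the score of fatty acid oxidation and ketogenesis (low-low 3 lowest) and 0.668 for the median signal of the array (low-high 3 highest). Among animals with low aggressiveness it was 0.749 for PJA1 and 0.728 for TFPI2 (high-low 2 lowest in both). Among the 4 females it was 0.914 for EIF1AY (low-low 1 lowest), 0.857 for LPIN2 and 0.835 for VPS36 (high-high 3 highest in both). EIF1AY in females (8.32 ± 4.37, SD, n = 4) lay below the lowest mean signal of a tested probe set, 40.58, so its gap was read from dim values. As log2(signal + 16), NR4A2 in animals with low stress response reached at most 5.92, near the lowest mean kept (5.82), and was dim too.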

How the results depend on the processing

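The settings without both arrays that stood apart, with the 3' to 5' ratio as a covariate and with 72 balanced splits, added constants of 1 and 64 for the simple effects, and the list tests for sex and the interaction, were chosen only after the data were seen. The counts of probe sets past the threshold for aggressiveness stayed at 0 under every alternative run. The count for stress response was 0 to 1 and that for the interaction 0 to 1 when single animals were left out, and the interaction gave 2 without both arrays that stood apart (OGDHL and ZNF687). Simple effects went from 2 probe sets to 0 with sex left out of the model, without the filter and without both arrays that stood apart, to 1 under quantile normalization, to 4 with an added constant of 1 and 0 with 64, and ranged from 0 to 2 with single animals left out. The count for sex went from 11 to 7 with the lowest 50% of probe sets left out, where fewer probe sets were tested. Lists called for stress response went from 8 to 0 with an estimated correlation, 5 without both arrays that stood apart (2 of the 8, with interferon-stimulated genes, cell cycle and neutrophil markers added) and 0 under 72 balanced splits. Lists called for aggressiveness went from 4 to 2 under quantile normalization and 7 with a variance trend, as robust estimation was not applied to lists. They went to 0 with an estimated correlation, 7 without both arrays that stood apart and 0 with the 3' to 5' ratio as covariate. Under 72 balanced splits 0 were called, and the number ranged from 0 to 8 with single animals left out. Under the balanced splits the number of splits itself allowed no single list to pass; otherwise the cause was not tested.

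Of the values of named genes under alternatives, 3035 kept their direction and side of the threshold, 37 lost a call, 9 gained one and 33 reversed. Of the 130 named genes in a comparison, PRKAG3, EIF1AY and CLSTN3 alone passed in the main fit. The rest had no call to lose, so the 3035 say little about how firm the calls were. Of the values of called lists, 437 kept direction and call, 81 lost the call and 0 reversed. Genes that reversed were all uncalled, and their values are log2 fold changes. For stress response PCK1 was -0.033 under median centring, and NR3C1 -0.088 in males only and -0.11 without both arrays that stood apart. For aggressiveness TAT was 6e-04 under quantile normalization and 0.023 with array weights, TSC22D3 0.067 with array weights, 0.16 in males only and 0.072 without both arrays that stood apart, HSD11B1 0.046 and 0.074 under the last pair of settings, and PER1 -0.025 in males only. With single animals left out the ranges for stress response were -0.052 to 0.16 for NR3C1, -0.015 to 0.038 for PCK1 and -0.32 to 0.0036 for TAT. For aggressiveness they were -0.12 to 0.063 for HSD11B1, -0.088 to 0.41 for SERPINA6, -0.13 to 0.078 for TSC22D3, -0.18 to 0.14 for TAT and -0.068 to 0.19 for PER1. The cause of these reversals was not tested. The males-only setting was not run for sex. The signal over background of dim probe sets limits what can be read of genes such as PROM1, GNG3, RGS16 and, in females, EIF1AY, whose mean signal in some groups was 16.6 or lower, and of PRKAG3 and ZNF281 (31 and 23.8).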

Other observations

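The list tests for sex, the members named from them the requirement that both correlation coefficients pass and the interval of r were chosen only after the results were seen. Genes of the urea cycle and amino acid catabolism, which dispose of nitrogen in the liver, were higher as a group in males than in females, with 17 of 18 above 0 and a median log2 fold change of 0.32 (camera, adjusted p = 6.75e-12, and adjusted p = 0.0269 with an estimated correlation; fry, adjusted p = 0.0186). Adjusted over the list alone, TAT, tyrosine aminotransferase, OAT, ornithine aminotransferase, and CTH, which makes cysteine, were higher, with log2 fold changes of 1.08 ± 0.27, 0.90 ± 0.22 and 0.61 ± 0.16 (SE). TAT had a signal of 9758 ± 2659 in males (SD, n = 8) and 4628 ± 1574 in females (SD, n = 4), and all 8 males lay above the median of the females. Genes of gluconeogenesis were higher as a group in males, with 11 of 13 above 0 and a median of 0.16 (adjusted p = 8.64e-05, and adjusted p = 0.0269 with an estimated correlation). Adjusted over the list alone, TAT, which is in both lists, GOT1, an aspartate aminotransferase, at 0.74 ± 0.20 (SE) and SLC37A4, the carrier of glucose 6-phosphate, at 0.54 ± 0.16 (SE) were higher, while PCK1 and FBP1, key enzymes of the pathway, had -0.01 ± 0.10 and -0.03 ± 0.11 (SE). The median of gluconeogenesis was 0.28 without low-low 1 and 0.11 without high-high 3, both females.

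The unfolded protein response list was lower as a group in males, with 17 of 18 genes below 0 and a median of -0.16 (adjusted p = 3.09e-04, and adjusted p = 0.671 with an estimated correlation). Its call ended without the female high-high 3 (-0.14, adjusted p = 0.0754) and without both arrays that stood apart (-0.15, adjusted p = 0.0986), and its median was -0.09 under median centring and -0.26 with the mean over the probe sets of a gene. HYOU1 had 2087 ± 490 in males (SD, n = 8) and 2877 ± 1245 in females (SD, n = 4), and no member passed when adjusted over the list alone. Oxidative phosphorylation was higher as a group in males, with 26 of 29 genes above 0 and a median of 0.10 (adjusted p = 8.64e-05, and adjusted p = 0.671 with an estimated correlation). Its median was 0.05 without high-high 3 and without both arrays that stood apart, and 0.17 under median centring. Fatty acid oxidation and ketogenesis was higher too, with 18 of 24 above 0 and a median of 0.15 (adjusted p = 0.0213, and adjusted p = 0.707 with an estimated correlation). That call ended without any of high-high 1 (0.09, adjusted p = 0.101), high-high 3 (0.02, 0.360), high-low 1 (0.12, 0.106), high-low 2 (0.09, 0.0677) or low-low 2 (0.11, 0.0607). It also ended without both arrays that stood apart (0.02, adjusted p = 0.357) and under quantile normalization (0.13, adjusted p = 0.0538), and its median was 0.24 without low-low 1 or low-low 3. No member of these last lists passed when adjusted over the list alone. As many lists as the 5 called for sex were called in 57 of 100 splits of the animals.

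A hypothesis was that animals with more transcript of the unfolded protein response may have less transcript of lipid synthesis and more of the acute phase, within groups. It was tested on the list scores of the 12 animals after stress response, aggressiveness and sex were taken out, with permutation tests in a family of 3 relations. For cholesterol synthesis Pearson's r was -0.721 (permutation p = 0.0074, adjusted p = 0.0186) and Spearman's rho -0.378 (permutation p = 0.229, adjusted p = 0.343), and r was -0.605 without the 2 animals farthest from the median. For fatty acid and triglyceride synthesis r was -0.689 (permutation p = 0.0124, adjusted p = 0.0186) and rho -0.490 (permutation p = 0.111, adjusted p = 0.334), and r was -0.600 without the 2 farthest. For the acute phase r was 0.0542 (permutation p = 0.867) and rho -0.035 (permutation p = 0.921), and r was 0.264 without the 2 farthest. The first 2 relations passed by r and not by rho, the prediction had not said which coefficient would decide, and both were required after this was seen, so neither was decided. For the acute phase neither coefficient passed, so the predicted relation was not seen. The 95% interval of r (Fisher) was -0.633 to 0.693, which leaves room for a relation either way. Residuals of a fitted model are not fully exchangeable, which limits these permutation tests.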
